A study of Ovis aries with 8 samples.

How the data were processed

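RNA of cultured fetal sheep hepatocytes was sequenced in 8 libraries, 4 basal and 4 treated with metformin, an antidiabetic biguanide. The labels number 4 cell preparations, each with 1 basal and 1 metformin library, and the series' design text gives a treatment of 24 h. The dose, the vehicle and the animals behind each preparation were not given in the sources used here. The p-values of the main fit therefore weigh the metformin change against its variation between preparations, and variation between animals is unknown. That variation was not taken from each gene alone, since its variance was drawn towards that of other genes (prior df 4.00). The labels record polyadenylated RNA purified with a column kit and a standard Illumina library preparation.

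The deposited table gives FPKM values (fragments scaled by transcript length and by the total mapped) per gene and library, made by the authors with Cufflinks on the Oar_v3.1 assembly, per the submitters' processing notes. The aligner, the annotation release and the tool versions were not given in the sources used here. FPKM divides by transcript length and by each library's total, so the number of reads behind a value is unknown, no counting interval is given, and a rise of some abundant transcripts lowers the FPKM of others. The table had 27057 rows. Of these, 18085 had a gene symbol, 8947 had none and 25 had a symbol that a spreadsheet had turned into a date; 3 gene identifiers occurred on 2 rows each, and 8221 rows were listed at 0 in all 8 libraries. A placeholder far above any expression value stood in 4 cells, 3 of AHSG and 1 of WBP1L, and was treated as missing. The FPKM of a library summed to between 1024543 and 1257764, and 12733 to 13293 genes reached an FPKM of 1.

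The authors' deposited table also holds the mean FPKM per group, a signed fold change of these means (a score, negative where metformin was lower), a p-value and, for part of the rows, a q-value. Recomputing them showed that the authors' deposited p-values equal a paired test of log2(FPKM + 1) for each gene alone, within 1e-06 for 18821 of 18832 rows. The deposited q-values cover 7209 rows. For 6183 of these the rounded group means differed by at least 5 FPKM, and 6173 of the 6183 q-values equalled a Benjamini-Hochberg adjustment over those rows alone, within 1e-05. The other 1026 rows share 1 repeated p-value, 0.391.

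Genes with an FPKM of at least 1 in at least 4 of the 8 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with the preparation as a block, a mean-variance trend and moderated variances, 2-sided. P-values were adjusted by Benjamini-Hochberg and the threshold was 0.05. Log2 changes are on the log2(FPKM + 1) scale, which understates the change of genes at low FPKM. Errors of log2 changes are standard errors from the moderated variances, so they do not give the spread of that gene alone between preparations. The pairing was checked before any calls were compared. Deviations from the group means correlated across genes between the basal and metformin library of one preparation, with r from 0.489 to 0.585 over the 4 pairs. Between libraries of different preparations r was at most 0.018. Centring on the group means lowers r between preparations where r within them is high, so these low values are no separate support for the pairing.

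Before the data were examined, 40 gene lists were fixed (pathways of liver metabolism and stress, hepatocyte products, and markers of other cell types of the liver), holding 910 entries, of which 773 matched a row. The 39 lists with at least 5 measured genes were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, beside camera with an estimated correlation and fry. The list of metformin transporters had 4 measured genes and was not tested. Another 10 lists were written after the results had been seen and are used in the closing observations alone. The genes named were chosen by a rule fixed beforehand: the 6 largest rises and the 6 largest falls among genes with a symbol that passed the threshold and moved the same way in all 4 preparations; genes fixed whatever their values (PPARGC1A, GDF15, FGF21, IGF2, IGFBP1, PCK1, G6PC, ATF4, NFE2L2, FASN and CPT1A); and, for each list past the threshold or with at least 3 members past it, up to 3 members with the lowest p. The rule took 133 genes, of which 3 are not reported here, and other genes named are said to have been chosen after their values were seen.

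The fit was tested on 10 simulated data sets of 13139 genes for the comparison of metformin with basal libraries, in which 200 genes were changed. It recovered 22.8% of genes changed 1.5-fold, 80.6% of those changed 2-fold and 96.9% of those changed 4-fold. Of the calls, 6.68% were unchanged genes, and no changed gene was called with the wrong sign. In 20 simulated data sets with no change and independent noise, camera called 0 lists. The simulation did not model correlation between genes. It also changed far fewer genes than the 5769 called in the data, and adjusted p depends on that share, so its rates need not hold here.

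Alternatives were the fit without the block, rescaling by the median of ratios, quantile normalization, no filter, a mean FPKM of at least 5, leaving out each preparation, a pseudocount of 0.1, limma without a trend, other thresholds, and the other set tests. A per-gene paired test without shared variance and the removal of rows named as small structural RNAs were added after seeing the data. Files were read and plotted with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9. Count-based tests were not used, since the table holds no counts. Genomic coordinates are not given, because no annotation of the Oar_v3.1 assembly was used here.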

Results

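The comparison asked how 24 h of metformin changed the transcriptome of fetal sheep hepatocytes, with 4 basal and 4 metformin libraries from the same 4 preparations. The depth of the libraries in reads is unknown. With the placeholder cells left out, the gene with the highest FPKM in all libraries was ATP6V0C, a proton pump subunit. AHSG could not be ranked in the libraries where it held a placeholder. ATP6V0C took 4.01% to 6.11% of the summed FPKM in basal and 5.37% to 7.05% in metformin libraries, and its share was higher with metformin in each preparation. Pearson correlations of log2(FPKM + 1) were 0.898 to 0.953 between basal libraries, 0.932 to 0.946 between metformin libraries and 0.904 to 0.951 between both libraries of one preparation.

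With metformin GDF15, a secreted stress cytokine, rose from 11.5 ± 6.55 to 103.8 ± 19.6 FPKM (SD, n = 4 per group), and the transcription factor ATF4 rose from 810.3 ± 176 to 1964 ± 373. HNF4A, a transcription factor of hepatocyte identity, fell from 55 ± 21.5 to 11.7 ± 3.78 FPKM, and CPT1A, which admits long-chain fatty acids to mitochondria, fell from 49.9 ± 21.6 to 15.7 ± 8.49. All 4 preparations moved the same way for each of these genes. Of 13141 genes tested with limma, 2605 rose and 3164 fell at an adjusted p under 0.05, which is 43.9% of the genes; 581 rose and 720 fell by at least 2-fold. Among the 5769 changed genes, 5663 moved the same way in all 4 preparations, which a call in a paired fit favours. Of all 13141 genes tested, 3682 were higher and 4228 lower in all 4 preparations, and the median log2 change was -0.04. Without preparation 1, 1679 genes rose and 1995 fell. Without the block, 1272 rose and 1246 fell, and the calls of 47 of the 130 named genes ended.

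**Figure D1:**
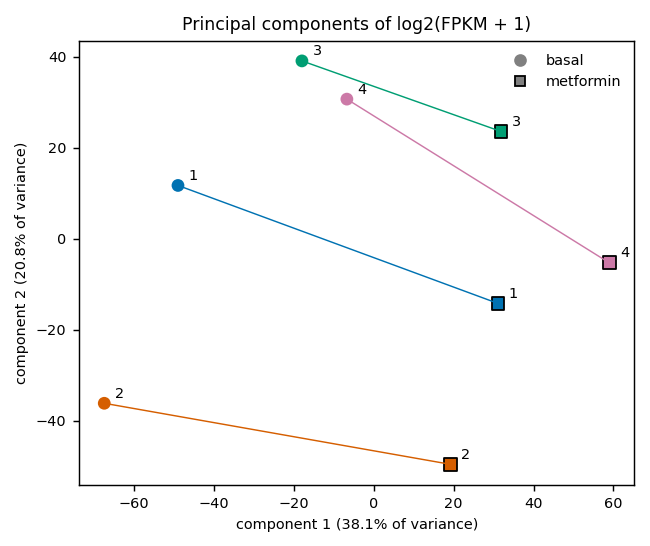
Principal components of log2(FPKM + 1) over the tested genes, with 1 point per library, a line joining both libraries of each preparation and numbers giving the preparation. Component 1 carried 38.1% of the variance and separated the basal from the metformin library within each preparation, and component 2 carried 20.8%.

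The largest rises of protein-coding genes were those of AREG, an epidermal growth factor receptor ligand, CRABP2, a retinoic acid carrier, IVNS1ABP and GDF15. AREG rose from 1.22 ± 0.695 to 27.5 ± 18.1 FPKM (log2 change 3.55 ± 0.19, SE). CRABP2 rose from 25.9 ± 12.3 to 266.7 ± 60.3 (3.44 ± 0.24), IVNS1ABP from 68.7 ± 24.0 to 671.8 ± 268 (3.24 ± 0.31), and the log2 change of GDF15 was 3.21 ± 0.32. The largest falls were those of DIRAS3, a RAS-related GTPase, from 527.1 ± 310 to 52.4 ± 22.7 FPKM (-3.18 ± 0.21), the splicing regulator ESRP2, from 39.0 ± 28.7 to 3.23 ± 1.83 (-3.02 ± 0.24), the amine oxidase AOC1 (-3.01 ± 0.16), the methionine adenosyltransferase MAT1A (-2.96 ± 0.22) and the organic anion transporter SLC22A7 (-2.93 ± 0.11). Adjusted p was between 0.000268 for SLC22A7 and 0.00105 for GDF15 over these 9 genes. The same rule took the small structural RNAs SNORA8 (4.68 ± 1.28), U1 (3.67 ± 0.92) and SNORD89 (-4.32 ± 1.39), with adjusted p of 0.0243, 0.0179 and 0.0416. SNORA8 and U1 were listed at 0 in 2 basal libraries and SNORD89 in 2 metformin libraries. Adjusted p was 0.0706 for SNORA8 and 0.0534 for U1 without preparation 1, 0.0681 and 0.0575 without preparation 2, and for SNORD89 0.143 without preparation 2 and 0.134 without preparation 3. The sizes of these changes are uncertain: without preparation 2 they were 3.24 for SNORA8, 2.73 for U1 and -3.05 for SNORD89, and over the alternatives tried they ranged from 3.24 to 6.34, from 2.73 to 5.33 and from -5.98 to -3.05. U1 has several rows in the table and near-identical copies in the genome, so its reads could be split between rows.

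Of the genes fixed beforehand, the hepatokine FGF21 rose from 0.756 ± 0.473 to 4.77 ± 1.34 FPKM (log2 change 1.73 ± 0.25, adjusted p = 0.00266), the growth factor carrier IGFBP1 from 995.0 ± 464 to 2909 ± 1160 (1.55 ± 0.32, adjusted p = 0.00948) and the mitochondrial coactivator PPARGC1A from 6.84 ± 2.02 to 15.7 ± 6.30 (1.04 ± 0.14, adjusted p = 0.00207). The log2 change of ATF4 was 1.28 ± 0.20 (adjusted p = 0.00358) and that of CPT1A was -1.65 ± 0.12 (adjusted p = 0.000683). The catalytic subunit of glucose-6-phosphatase, G6PC, fell from 11.6 ± 11.2 to 1.78 ± 2.43 FPKM (-2.13 ± 0.20, adjusted p = 0.000976). PCK1, the other gluconeogenic gene fixed, rose from 0.711 ± 0.638 to 1.83 ± 0.598 FPKM in 3 of 4 preparations (0.78 ± 0.24, adjusted p = 0.0368), a call that ended without preparation 1, 3 or 4, with adjusted p of 0.0828, 0.104 and 0.108. IGF2 fell from 485.2 ± 85.0 to 329.2 ± 86.5 (-0.59 ± 0.14, adjusted p = 0.0169), and its adjusted p was 0.0604 without preparation 3 and 0.0630 without preparation 4. Without the block the calls of G6PC, PCK1 and IGF2 ended. No change past the threshold was found for NFE2L2 (0.16, 95% interval -0.08 to 0.41, adjusted p = 0.231) or FASN (0.00, -0.33 to 0.32, adjusted p = 0.984).

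**Figure D2:**
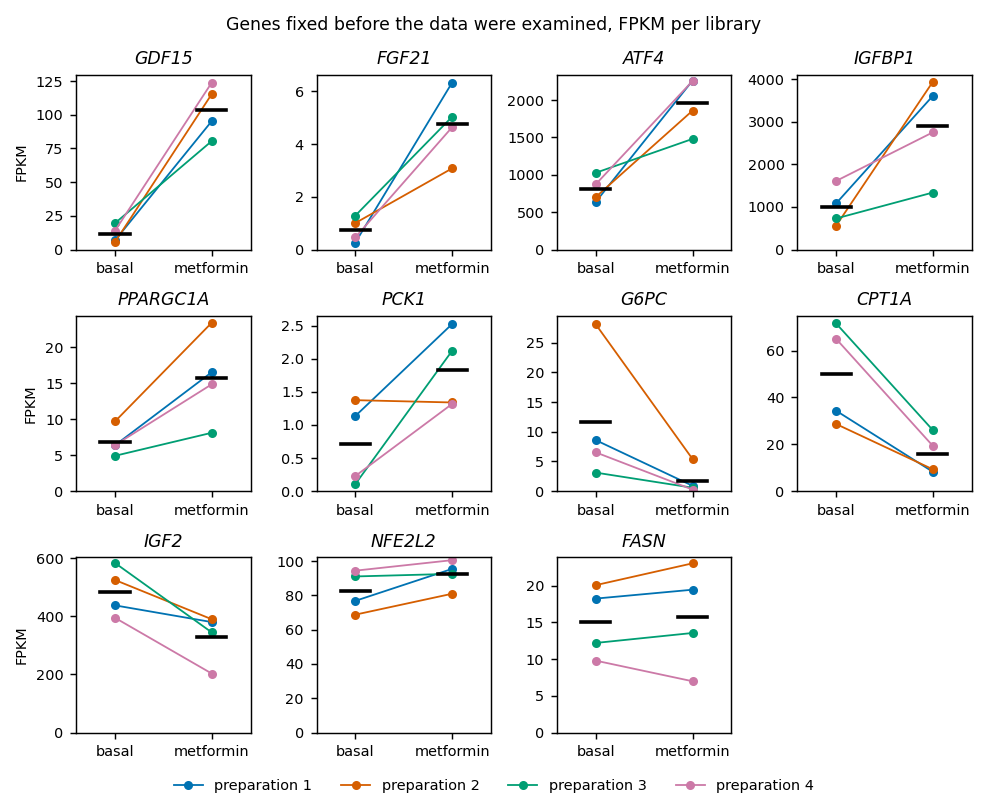
FPKM of 11 genes fixed beforehand, in panels with their own axes starting at 0. Points are libraries, coloured lines join both libraries of a preparation and black bars are group means (n = 4). The mean of GDF15 went from 11.5 to 103.8 FPKM, and that of G6PC from 11.6 to 1.78.

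Of the 39 lists tested with camera, 7 rose and 10 fell at an adjusted p under 0.05 with the preset correlation. None passed with an estimated correlation, where the lowest adjusted p was 0.718, the value of all 17; the lowest unadjusted p was 0.0804, and 0 lists had one under 0.05. With fry, which does not compare a list with other genes, 18 lists passed, and the integrated stress response, the unfolded protein response, the immediate early, the inflammatory, the stellate and the endothelial lists did not. Of these 18, 7 did not pass camera: gluconeogenesis (fry adjusted p = 0.0418), the hepatokines (0.0256) and the urea cycle (0.0418), downward, and hypoxia targets (0.0447), autophagy (0.0479), erythroid (0.0447) and cholangiocyte markers (0.0447), upward. Without the block 3 lists passed camera: the integrated stress response, p53 targets and proliferation. Quantile normalization ended the calls of heat shock genes, the unfolded protein response, insulin signalling, growth and immediate early genes and inflammatory genes, and the median of ratios that of the growth and immediate early genes; a mean FPKM of at least 5 ended those of the bile acid, immediate early, insulin and inflammatory lists, and testing without a filter that of the fetal list. For 24 of the 40 lists the counts adjusted over the list alone equalled those over all genes, and for the other 16 both are given.

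The integrated stress response, the ATF4-driven program of translational stress, had 18 of 32 measured members rise and 1 fall (camera adjusted p = 6.29e-05, and adjusted p = 0.718 with an estimated correlation). DDIT3, a transcription factor linked to stress-induced cell death, rose from 53.9 ± 15 to 253.9 ± 67.9 FPKM, PPP1R15A, which helps reverse the stress phosphorylation of eIF2, from 53.4 ± 7.96 to 248.8 ± 68.6, and the lipoprotein receptor VLDLR from 50.2 ± 7.81 to 138.3 ± 30.4. The amino acid synthesis genes ASNS, PHGDH and PSAT1 of this list, chosen after their values were seen, had log2 changes of -0.02, 0.12 and 0.40 that did not pass the test. The unfolded protein response of the endoplasmic reticulum had 9 of 23 members rise and 0 fall (adjusted p = 0.0205, and adjusted p = 0.718 with an estimated correlation), among them the chaperone HSPA5, from 465.1 ± 136 to 1054 ± 419, DNAJB9, from 60.3 ± 9.43 to 156.9 ± 46.4, and ATF6, from 28.6 ± 4.31 to 54.2 ± 5.36. Its adjusted p was 0.0770 without preparation 4.

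Heat shock and mitochondrial chaperones had 5 of 14 members rise and 0 fall (adjusted p = 0.0186, and adjusted p = 0.718 with an estimated correlation). They included HSPB8, from 257.0 ± 52.2 to 718.2 ± 256 FPKM, HSPA8 and the mitochondrial HSPA9, whose log2 changes were 1.43, 0.61 and 0.68; the adjusted p of HSPA9 was 0.0504 without preparation 1. Of 19 p53 targets and apoptosis genes 11 rose and 2 fell, or 12 and 2 adjusted over the list alone (adjusted p = 0.0014, and adjusted p = 0.718 with an estimated correlation). CDKN1A, an inhibitor of cell cycle kinases, rose from 78.5 ± 23.9 to 303.9 ± 73.8 FPKM, PLK3 from 14.6 ± 3.79 to 41.0 ± 4.12 and PLK2 from 78.7 ± 22.4 to 220.4 ± 63.2. NRF2 targets had 7 of 23 rise and 3 fall and did not pass camera (adjusted p = 0.387), with a mean log2 change of 0.15 and a median of -0.05. MAFG rose by 1.32 and SRXN1 by 1.04 on the log2 scale, and the epoxide hydrolase EPHX1 fell by 1.58.

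Of 26 proliferation genes 22 fell and 0 rose, or 24 and 0 adjusted over the list alone (adjusted p = 2.04e-07, and adjusted p = 0.718 with an estimated correlation). RRM2, the small subunit of ribonucleotide reductase, fell from 26.2 ± 6.61 to 5.78 ± 1.24 FPKM, and the replication helicase genes MCM4 and MCM5 fell from 42.3 ± 12.2 to 14.8 ± 4.41 and from 48.7 ± 13.8 to 19.1 ± 3.68. Growth and immediate early genes had 11 of 24 rise and 5 fall, or 13 and 6 adjusted over the list alone (adjusted p = 0.0346, and adjusted p = 0.718 with an estimated correlation). The phosphatase gene DUSP1 rose from 72.6 ± 10.8 to 196.6 ± 30.0 and the transcription factor gene KLF4 from 19.4 ± 4.48 to 56.7 ± 21.8, whereas CCND1, which encodes cyclin D1, fell from 43.3 ± 17.8 to 18.2 ± 9.17. This list did not pass without preparation 4 (adjusted p = 0.0855) or under either rescaling of the libraries.

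Of 27 secreted hepatocyte proteins 17 fell and 2 rose, or 19 and 2 adjusted over the list alone (adjusted p = 0.00062, and adjusted p = 0.718 with an estimated correlation). AMBP fell from 1659 ± 768 to 818.3 ± 448 FPKM and TTPA, a vitamin E carrier, from 28.2 ± 15.8 to 10.6 ± 5.80, whereas coagulation factor F5 rose from 65.3 ± 7.95 to 147.5 ± 24.6. Complement and acute phase genes had 9 of 14 fall and 0 rise, or 10 and 0 adjusted over the list alone (adjusted p = 0.0014, and adjusted p = 0.718 with an estimated correlation), with log2 changes of -2.10 for C5, -1.70 for C8B and -1.05 for CFI. Fetal hepatoblast genes had 5 of 11 fall and 1 rise (adjusted p = 0.0343, and adjusted p = 0.718 with an estimated correlation), and the list did not pass without preparation 3 (adjusted p = 0.0775). PEG10 fell from 2612 ± 1581 to 511.2 ± 358, PEG3 from 183.3 ± 67.1 to 73.6 ± 24.0 and alpha-fetoprotein, AFP, from 217.4 ± 197 to 98.0 ± 90.2. Without the block the calls of AMBP, TTPA, C8B, CFI and AFP ended. In the same libraries 9 of 16 stellate and fibroblast markers fell and 1 rose, and 8 of 16 endothelial markers fell and 0 rose. Both lists had an adjusted p of 0.718 with an estimated correlation and a fry adjusted p of 0.0620.

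Of 23 genes of fatty acid oxidation and ketogenesis 14 fell and 5 rose (adjusted p = 0.0307, and adjusted p = 0.718 with an estimated correlation). Beside CPT1A, the peroxisomal enzyme gene EHHADH fell from 57.0 ± 24.2 to 20.9 ± 9.59 FPKM and ACSL4 from 263.9 ± 41.2 to 110.9 ± 10.3. Of 19 genes of amino acid catabolism 10 fell and 0 rose (adjusted p = 0.0167, and adjusted p = 0.718 with an estimated correlation), among them MAT1A, from 82.9 ± 67.7 to 8.72 ± 6.53, HGD, from 20.8 ± 14.2 to 5.15 ± 3.36, and AGXT, from 47.1 ± 28.4 to 14.5 ± 8.06. Bile acid synthesis and transport had 6 of 11 fall and 1 rise (adjusted p = 0.0307, and adjusted p = 0.718 with an estimated correlation). AKR1D1 fell from 21.1 ± 13.6 to 2.28 ± 1.66, and the canalicular transporter genes ABCC2 and ABCG5 had log2 changes of -1.88 and -1.03; without preparation 2 the list's adjusted p was 0.0542. The urea cycle list had 6 of 12 fall and 1 rise, or 7 and 3 adjusted over the list alone, and did not pass camera (adjusted p = 0.188). Its first enzyme, CPS1, fell from 126.8 ± 108 to 25.1 ± 26.8, GLUD1 from 711.5 ± 148 to 368.3 ± 86.8 and OTC from 12.9 ± 11.7 to 3.62 ± 3.17.

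**Figure D3:**
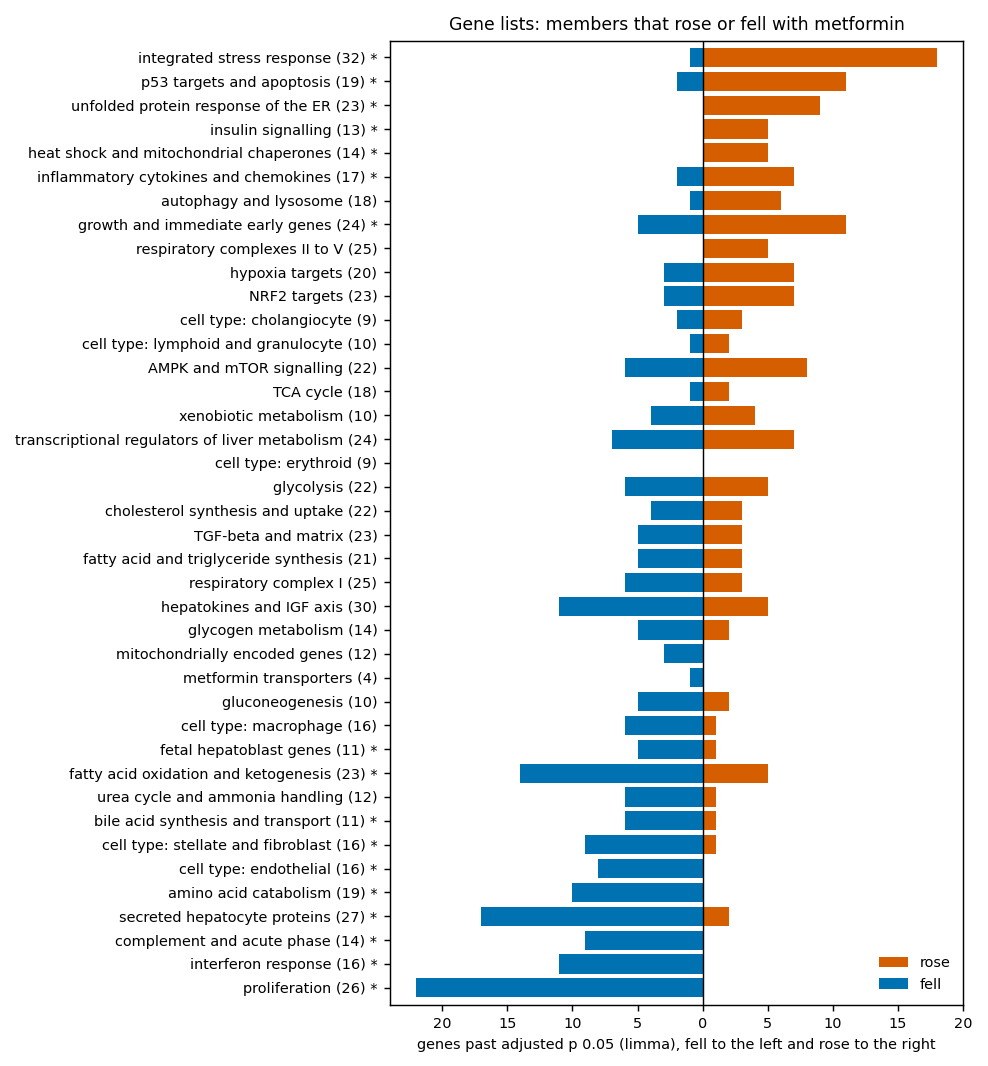
Members of each of the 40 gene lists that rose (right) or fell (left) with metformin at a limma adjusted p under 0.05, with the number of measured members in parentheses and an asterisk for lists past an adjusted p of 0.05 with camera at the preset correlation. Proliferation had 22 members fall and the integrated stress response had 18 rise.

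Lists of glucose metabolism did not pass camera. Gluconeogenesis had 5 of 10 members fall and 2 rise (adjusted p = 0.554): FBP1 fell from 145.7 ± 84.7 to 36.5 ± 23.6 FPKM and G6PC3 from 36.2 ± 7.41 to 16.7 ± 5.45. Glycolysis had 5 of 22 rise and 6 fall (adjusted p = 0.884), with a mean log2 change of 0.09 and a median of -0.10. The glucose transporter SLC2A1 rose from 54.9 ± 27.5 to 204.7 ± 42.4, and PFKFB3 and PFKFB4, which make an activator of glycolysis, rose from 23.3 ± 6.37 to 82.7 ± 30.6 and from 7.55 ± 1.24 to 20.1 ± 4.23. Glycogen metabolism had 5 of 14 fall and 2 rise (adjusted p = 0.463). Liver glycogen synthase GYS2 fell from 43.1 ± 15.7 to 16.7 ± 9.10, while the muscle-type GYS1 and the phosphatase subunit PPP1R3C rose from 10.1 ± 0.708 to 22.7 ± 5.89 and from 48.5 ± 13.3 to 120.6 ± 39.2.

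Insulin signalling genes had 5 of 13 members rise and 0 fall (adjusted p = 0.0386, and adjusted p = 0.718 with an estimated correlation). The receptor INSR rose from 23.4 ± 5.77 to 70.1 ± 27.2 FPKM, its substrate IRS1 from 64.0 ± 8.52 to 230.4 ± 52.4 and PIK3CA from 18.5 ± 3.95 to 30.2 ± 3.41. The list did not pass without preparation 1 (adjusted p = 0.0691) or 2 (adjusted p = 0.0542). AMPK and mTOR signalling had 8 of 22 rise and 6 fall (adjusted p = 0.269). The folliculin partners FNIP1 and FNIP2 rose by 1.79 and 1.56 on the log2 scale and SESN3 fell by 1.37. Hepatokines and the IGF axis had 5 of 30 rise and 11 fall, or 5 and 12 adjusted over the list alone (adjusted p = 0.269). INHBA rose from 5.72 ± 3.46 to 21.5 ± 9.59 and LECT2 fell from 313.8 ± 261 to 85.5 ± 69.3. Transcriptional regulators of liver metabolism had 7 of 24 rise and 7 fall, or 8 and 7 adjusted over the list alone (adjusted p = 0.629, mean log2 change -0.07, median 0.16 and the camera direction up). PROX1 fell with HNF4A, from 29.9 ± 14.0 to 7.15 ± 3.65, and the clock gene NR1D2 rose from 29.2 ± 6.26 to 82.6 ± 13.3. Of the 4 measured metformin transporters, 1 fell and 0 rose. That gene, SLC22A5, was chosen after its value was seen (3.74 ± 1.09 to 1.45 ± 0.250 FPKM).

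Mitochondrial lists did not pass camera. Complex I had 6 of 25 members fall and 3 rise (adjusted p = 0.773), with log2 changes of -0.84 for NDUFA6, -0.63 for NDUFA2 and 0.62 for NDUFV3. Complexes II to V had 5 of 25 rise and 0 fall, or 4 and 0 adjusted over the list alone (adjusted p = 0.142): SDHB by 0.53, UQCRC1 by 0.59 and ATP5G1 by 0.56. Mitochondrially encoded genes had 3 of 12 fall and 0 rise, or 1 and 0 adjusted over the list alone (adjusted p = 0.153): ND4L by -0.63, ND6 by -0.38 and ND4 by -0.41. The tricarboxylic acid cycle had 2 of 18 rise, ACO1 by 0.44 and DLD by 0.42, and 1 fall, PDK3 by -0.56, or 1 and 1 adjusted over the list alone (adjusted p = 0.463). The calls of UQCRC1, ATP5G1, ND6, ND4, ACO1, DLD and PDK3 ended on leaving out at least 1 preparation, with adjusted p of at most 0.117; those of ND4 ended without any 1 of the 4.

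Lipid synthesis lists did not pass camera. Cholesterol synthesis had 3 of 22 members rise and 4 fall (adjusted p = 0.645), and fatty acid and triglyceride synthesis had 3 of 21 rise and 5 fall (adjusted p = 0.887). INSIG1, a regulator of sterol synthesis, rose from 37.2 ± 23.8 to 115.7 ± 83.6 FPKM, with CYP51A1 (log2 change 0.86). MLXIPL, a carbohydrate-responsive transcription factor gene, fell by 1.33, GPAM fell by 1.52 and DGAT2 fell by 1.29 on the log2 scale. Xenobiotic metabolism had 4 of 10 rise and 4 fall (adjusted p = 0.885; mean -0.02 and median -0.02 log2, camera direction up). CYP3A24 rose from 19.9 ± 22.7 to 129.9 ± 96.7, CYP1A1 fell from 20.5 ± 12.1 to 3.65 ± 2.29 and ALDH1A1 fell from 49.2 ± 8.66 to 18.8 ± 5.22. Reads of cytochrome P450 genes could be split between near-identical copies.

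Of 17 inflammatory cytokine and chemokine genes 7 rose and 2 fell (adjusted p = 0.0307, and adjusted p = 0.718 with an estimated correlation). LIF, a cytokine of the interleukin 6 family, rose from 7.70 ± 3.80 to 39.1 ± 22.3 FPKM, PTGS2 from 41.3 ± 36.9 to 106.4 ± 85.1 and RELB from 24.5 ± 4.14 to 59.8 ± 4.15. The list did not pass without preparation 3 (adjusted p = 0.0618) or 4 (adjusted p = 0.0868). Interferon response genes had 11 of 16 fall and 0 rise, or 12 and 0 adjusted over the list alone (adjusted p = 0.00065, and adjusted p = 0.718 with an estimated correlation): IFI44, OAS2 and IFIT5 had log2 changes of -1.42, -1.58 and -0.98. All 16 had their highest basal value in preparation 1. Hypoxia targets had 7 of 20 rise and 3 fall, or 7 and 4 adjusted over the list alone (adjusted p = 0.269). BHLHE41 rose from 13.4 ± 2.22 to 94.0 ± 33.9 and NDRG1 from 185.2 ± 92.4 to 592.8 ± 125, and EGLN1 fell from 60.3 ± 10.0 to 30.3 ± 8.61. Autophagy and lysosome genes had 6 of 18 rise and 1 fall (adjusted p = 0.129), with the lysosomal protease CTSB going from 1025 ± 677 to 2842 ± 1315, the autophagy receptor SQSTM1 from 732.1 ± 276 to 1759 ± 238 and MCOLN1 from 39.5 ± 8.58 to 61.6 ± 9.92. TGF-beta and matrix genes had 3 of 23 rise and 5 fall, but 0 and 0 adjusted over the list alone, where 11 had an unadjusted p under 0.05 (camera adjusted p = 0.688, mean log2 change -0.01, median 0.18 and the camera direction up). SMAD7 rose by 0.75, and TGFB1 and TIMP1 fell by 0.42 and 0.69; the last 2 calls ended without preparation 3 (adjusted p = 0.0630 and 0.0709) or 4 (adjusted p = 0.0829 and 0.0599), and that of TGFB1 also without preparation 1 (adjusted p = 0.0760).

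Markers of other liver cell types were measured in the same libraries. Stellate and fibroblast markers had 9 of 16 fall and 1 rise, or 11 and 1 adjusted over the list alone (adjusted p = 0.0185, and adjusted p = 0.718 with an estimated correlation): ACTA2 fell from 906.2 ± 407 to 579.5 ± 309 FPKM, LUM from 31.5 ± 14.2 to 20.02 ± 9.43 and THY1 from 4.18 ± 2.92 to 2.47 ± 2.63. Endothelial markers had 8 of 16 fall and 0 rise, or 10 and 0 adjusted over the list alone (adjusted p = 0.0198, and adjusted p = 0.718 with an estimated correlation), with log2 changes of -0.94 for CLEC14A, -0.58 for TEK and -0.61 for STAB1; the call of STAB1 ended without preparation 2, 3 or 4 (adjusted p of 0.0725, 0.0578 and 0.0511). Macrophage markers had 6 of 16 fall and 1 rise (adjusted p = 0.219): C1QB and CSF1R fell by 0.55 and 0.58 on the log2 scale and CD68 rose by 0.72. Cholangiocyte markers had 3 of 9 rise and 2 fall (adjusted p = 0.463), with rises of SOX9 (log2 change 1.31) and CLDN4 (0.82). None of 9 erythroid markers changed with limma, 2 having an unadjusted p under 0.05 (camera adjusted p = 0.153). Lymphoid and granulocyte markers had 2 of 10 rise and 1 fall (adjusted p = 0.651). The T cell receptor subunit CD3G rose from 0.864 ± 0.555 to 6.01 ± 1.44, CD3D rose by 0.84 on the log2 scale, and S100A8 fell by 0.76. The call of CD3D ended without preparation 1, 2 or 4 (adjusted p of 0.0682, 0.0729 and 0.0572). CD3E, chosen after its value was seen, had a log2 change of -0.31 that did not pass. Without the block the calls of ACTA2, LUM, THY1, CLEC14A, TEK, STAB1, C1QB, CSF1R, CD68 and S100A8 ended.

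A q-value under 0.05 was given to 2696 genes in the authors' deposited table, 1424 higher and 1272 lower with metformin. Of these, 1360 were higher and 1229 lower in the limma fit as well, 64 and 43 passed in the authors' table alone, and none had opposite directions. Both used the same 8 libraries and pairs, so the shared directions are not independent support. The limma fit called a further 1245 genes higher and 1935 lower. The authors' p-values adjusted over all 18834 rows that have one gave 33 genes under 0.05. That count depends on the rows included: a per-gene paired test adjusted over the 13141 genes of the limma fit gave 1653. Among rows that kept a q-value, leaving out those with the repeated p, 63.3% had a p-value under 0.05, against 21.7% of the rows without one. Of these 6050 rows, 6047 had group means that differed by at least 5 FPKM. They were thus selected on the difference itself, which favours small p-values.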

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

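The test for an outlying library was fixed in advance; the tests of explanations for the secreted hepatocyte proteins and the test of other splits were chosen only after the results were seen. A library was taken as outlying where its gap to the nearest of the other 3 libraries of its group was large against the range of the group. Of 270 groups (130 named genes and 5 library measures, in basal and in metformin libraries), 23 had an outlying library. The cutoff gives about 13.5 for independent, normally distributed values. FPKM values of genes from the same libraries need be neither, so whether 23 exceeds chance was not tested.

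All 16 measured interferon response genes were highest in preparation 1 among the basal libraries, and 15 among the metformin libraries, the exception being MX1. OAS2 was at 90.0 FPKM in its basal library, against 7.34 to 11.3 in the others, and at 20.7 with metformin. IFI44 was at 14.8 in its basal and 4.23 in its metformin library, and IFIT5 at 62.7 in its metformin library. UQCRC1 in the metformin library (224 FPKM) and SMAD7 in the basal library (38.7) of this preparation were also the highest of their groups. The metformin library of preparation 2 held 6 outlying values: the highest ESRP2 (5.95 FPKM), G6PC (5.40), PROX1 (12.6), ABCC2 (2.83) and PEG10 (1042) of the group, and the lowest CD68, at 636 against 1039 to 1060. Its basal library had the highest CPS1 (288) and AGXT (89.4).

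In preparation 3 the basal library had the lowest CYP1A1 (2.49 FPKM, against 25.9 to 27.7) and NDUFA2 (191) and the highest INHBA (10.9), and the metformin library the highest THY1 (6.38) and CSF1R (93.1). In preparation 4 U1 was at 468 FPKM in the metformin library, against 35.3 to 93.4 in the others, and FNIP1 at 25.4 in the basal library. The metformin library of preparation 4 had the largest FPKM sum, 1257764, against 1138642 to 1152845. All these genes kept their calls on leaving out any 1 preparation, except U1 and UQCRC1.

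Of 27 secreted hepatocyte proteins 17 fell and 2 rose. A lower share of hepatocytes in the treated cultures would raise the markers of every other type alike only if those types kept their proportions. That narrow case is argued against by 3 types with a mean log2 change below 0 in all 4 preparations. They are stellate and fibroblast (-0.86 to -0.29), endothelial (-0.67 to -0.12) and macrophage (-0.32 to -0.07). A lower share of hepatocytes with unequal changes of the other types cannot be excluded by these markers. Cholangiocyte (0.06 to 0.36) and erythroid markers (0.14 to 0.32) had a mean above 0 in all 4 and lymphoid markers in 3, so a gain of these types stays open. Under both the median of ratios and quantile normalization 16 of the 17 proteins still fell, so their fall did not depend on the choice among these scalings. The 17 were picked for falling, and neither scaling can detect a shift shared by most genes, so such a shift stays open. A mean change below 0 in each of the 4 preparations (-0.34 to -0.83) restates the choice of a list that was called lower, so a response of the preparations to metformin stays open and no biological explanation was tested.

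Libraries were also regrouped. Of 35 splits of the 8 libraries into equal groups, 8 parted all 4 pairs, the real one included, which is too few for a share under 0.05; 1 of the 8, the real one, gave as many genes and 1 as many lists. The real split called 5769 genes, and the highest of the other 7 called 1. The other 7 exchanged 1 or 2 pairs, which puts treatment change into the residual variance and lowers gene calls. Their gene and list counts are therefore not those of libraries without a treatment change. For gene lists at the preset correlation the real split called 17. Of the other 7, 4 exchanged 1 pair, which keeps part of the treatment contrast, and called 7 to 11 lists, and 3 exchanged 2 pairs and called 9 to 14. A further 24 splits parted only 2 pairs and called 0 to 8 genes: the 12 that kept the treatment contrast in these pairs called 8 to 16 lists, and the 12 that exchanged 1 of them called 4 to 13.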

How the results depend on the processing

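The per-gene paired test and the fit without small structural RNAs were chosen only after the result was seen. No gene named and called by limma changed direction under any alternative. Without the block 1272 genes were higher, 1246 lower and 3 lists passed; an adjusted p of 0.01 gave 1329 and 1571 genes, a 1.5-fold minimum 1544 and 2057, and a per-gene paired test without limma's shared variance 766 and 887. Leaving out 1 preparation gave 1679 to 2307 genes higher and 1995 to 2923 lower, with fewer samples fitted. With an estimated correlation 0 lists passed. The stricter thresholds lower the counts by construction, and for the other changes the cause was not tested. The remaining settings stayed within 1.5 times: the median of ratios gave 2923 and 3245 genes, quantile normalization 2975 and 2899, no filter 2101 and 2632, and a mean FPKM of at least 5 gave 2355 and 2318. FASN, which passed no threshold, changed sign: it was 0.0046 with the median of ratios, 0.0493 with quantile normalization and -0.0686 to 0.14 on leaving out 1 preparation. Of 130 named genes, calls ended for 47 without the block (adjusted p of 0.0512 to 0.55), for 51 with the per-gene paired test (0.0501 to 0.214), 32 of them in both, for 24 at an adjusted p of 0.01, for 11 with the 1.5-fold minimum and for 8 with no filter. Without the block those of AFP (adjusted p = 0.525), OAS2 (0.23), IFI44, PTGS2, CCND1, AOC1, LECT2, OTC, CYP1A1 and CYP3A24 were among them, and with the paired test those of ATF4, FGF21, IGFBP1 and HSPA5. Leaving out a preparation ended the calls of 17 named genes and 6 lists. With a pseudocount of 0.1 the log2 changes of genes with low values lay farther from 0, among them AREG (4.38), G6PC (-3.00), FGF21 (2.65), PCK1 (1.65), ABCC2 (-2.71), ABCG5 (-1.69), CD3G (2.94) and CD3D (1.73). Depth in reads is unknown, so its limit on low genes was not measured.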

Other observations

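The 10 gene lists here were written after the results were seen, and their tests, with those of scaling, stellate cells and small structural RNAs, were chosen only after the result was seen; the test without the genes seen first was set before its result. Genes of DNA repair and replication had 24 of 32 members fall and 1 rise (camera adjusted p = 1.18e-06, and adjusted p = 0.281 with an estimated correlation). CHEK1, a checkpoint kinase, fell from 18.0 ± 4.65 to 4.81 ± 1.5 FPKM (SD, n = 4), and the primase subunit PRIM1, seen before the list was written, from 11.4 ± 2.46 to 4.28 ± 1.10. Subunits of the vacuolar proton pump had 7 of 18 rise and 1 fall (adjusted p = 0.00423, and adjusted p = 0.548 with an estimated correlation). The abundant subunit ATP6V0C was not among the 18. TCIRG1, seen first, rose from 78.3 ± 28.4 to 316.3 ± 93.4 and ATP6V1C1 from 39.8 ± 18.7 to 119.5 ± 64.0. Ligands of the epidermal growth factor family had 3 of 5 rise and 0 fall (adjusted p = 0.00595, and adjusted p = 0.281 with an estimated correlation), with EREG and HBEGF beside AREG, which was seen first. The camera p of these lists include PRIM1, TCIRG1 and AREG, were not computed without them and so partly restate the choice. Genes named in this part were chosen after their values were seen.

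Of the other lists, 6 did not pass camera, and with fry those of junctions (adjusted p = 0.0220) and the clock (adjusted p = 0.0243) passed. Tight and gap junction genes had 3 of 16 rise and 7 fall, or 4 and 7 adjusted over the list alone, and the hepatocyte gap junction gene GJB1, seen first, fell from 204.6 ± 122 to 42.7 ± 25.6 FPKM. Circadian clock genes had 5 of 14 rise and 4 fall, or 6 and 5 adjusted over the list alone, with a rise of CRY1 from 9.30 ± 2.83 to 28.1 ± 6.42. Lysosomal genes had 7 of 28 rise and 3 fall, and the mitochondrial ribosome 6 of 63 rise and 6 fall, or 3 and 5 adjusted over the list alone. Proteasome subunits had 2 of 27 rise and 0 fall and ribosome biogenesis 1 of 30 rise and 3 fall with limma, but both had 0 and 0 adjusted over the list alone, where 7 and 9 had an unadjusted p under 0.05.

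Genes imprinted in other mammals were mostly lower with metformin. Of 19 measured, 11 fell and 1, GRB10, rose (mean log2 change -0.92, camera adjusted p = 0.000232, and adjusted p = 0.281 with an estimated correlation), and NNAT fell from 1298 ± 1749 to 174.9 ± 229 FPKM. DIRAS3, PEG10, PEG3 and IGF2 were seen before the list was written. Of the other 15 genes 7 fell and 1 rose, with a camera p of 0.00354 (p = 0.0841 with an estimated correlation). The preset correlation also called 9 to 14 of the lists fixed beforehand in regrouped libraries that exchanged 2 pairs. The other 15 genes were also listed after the results were seen, so choice of the genes stays open. All 11 genes still fell under both scalings, so their fall did not depend on the choice among these scalings. The 11 were picked for falling, and neither scaling can detect a shift shared by most genes, so such a shift stays open. The intervals of 4 genes, PEG10, NNAT, DIRAS3 and SGCE, lay below the change of every stellate marker (lowest TAGLN, -1.09). These 4 fell further than a loss of stellate cells and fibroblasts that lowered all their transcripts like the markers would give. The error of TAGLN was not counted, and loss of only some of these cells was not tested, so such a loss stays open. It may account for the other 7 that fell, whose intervals reach into the range of the markers. A joint response of the imprinted genes to metformin was not tested apart from the fall of the secreted hepatocyte proteins.

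Of 63 small structural RNAs tested, which lack long poly(A) tails, 13 rose and 3 fell (exact binomial p = 0.0213). Of the 13, 11 had their highest metformin value in the library of preparation 4; without that preparation 8 rose and 2 fell (exact p = 0.109), and 9 and 3 without preparation 3 (exact p = 0.146), 11 and 0 without preparation 2 (exact p = 0.000977) and 12 and 3 without preparation 1 (exact p = 0.0352). Near-identical copies and shared libraries make these genes dependent, so chance calls among short genes with a large spread stay open, as does weaker selection of polyadenylated RNA in the treated libraries, which may contribute. Their median log2 change was 0.552, below the 2.38 of those that rose by more than the median absolute deviation of 1.07, a bound first written as evidence against weaker selection. That bound was dropped after the value was seen, because the 13 were picked for passing and the spread within groups was 2.94 log2 against 0.29 for other genes, so the explanation stays open.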
